A study of Homo sapiens with 8 samples.

How the data were processed

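Total RNA of vastus lateralis biopsies from 4 people without cirrhosis and 4 people with cirrhosis was sequenced by the authors on an Illumina HiSeq instrument, with 1 library per person. The deposited table gives FPKM values made by the authors for 60448 gene identifiers in the 8 libraries. The submitters' processing notes name STAR, TopHat, HTSeq and DESeq2 without versions and the genome build hg19. The annotation is not given in the sources used here. Gene names were taken from GENCODE release 29, which named 56868 identifiers and left 3580 without a name. No coordinates were used. Before any test, 1224 identifiers that could reveal a donor's sex or genotype were left out, which held 0.208% of the reads.

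The unit was checked on the values. Ratios of a gene's FPKM between libraries were ratios of whole numbers for 100% of the genes, with a tolerance of 0.001 reads, so whole read numbers per gene and the total of each library could be recovered. The totals ran from 19678809 to 24753733 counted reads. A single read on a gene of 1 kilobase was worth 0.0404 to 0.0508 FPKM. These figures describe counting only, since reads without molecular identifiers are not independent molecules. No library was a near copy of another, since the lowest chi-square per degree of freedom between the read numbers of a pair was 44.4.

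Values were analysed as log2(FPKM + 1) for the 12746 genes with a mean FPKM of at least 1 over the 8 libraries. The groups were compared, cirrhosis minus control, with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Figures and tables of reads were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The replicate numbers of the 2 groups belong to different people, so no pairing was used.

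A set of 48 gene lists, 36 of pathways and 12 of cell type markers, was fixed before the data were examined, as were the tests, the threshold and most of the alternative settings. Lists with at least 5 measured members were tested, which left out the B and plasma cell list with 2 measured members (median log2 difference 0.08) and the keratinocyte list with 3 (median 0.23). The remaining 46 lists were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The test of fry named PValue asks whether the genes of a list move, on balance, one way, and its mixed test asks whether they change in either direction. Members of each list were also adjusted over the list alone, which takes no account of the number of lists. A list score is the mean over members of log2(FPKM + 1) less the gene's mean over the 8 libraries, and scores were compared by an exact two-sided permutation test over 70 assignments.

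The genes named in the text follow a rule with 3 parts. The first part takes the 10 genes with the largest change in each direction among those past the threshold with groups that do not overlap, filled up, where fewer pass, by the genes with non-overlapping groups and the smallest unadjusted p. The second part is GLUL, MSTN, FBXO32, TRIM63, ATF4, DDIT3, PPARGC1A and CDKN1A. The third part takes the 3 to 4 members with the smallest p from each list that passed camera or had at least 3 members past the threshold. Pseudogenes and uncharacterised names were not named. The other clock genes, AMPD3, ARG2 and the genes of the other observations were chosen after their values were seen.

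The alternative settings fixed at that stage were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, rescaling by median ratios, quantile normalization, and leaving out the mitochondrially encoded and the 10 most abundant genes. Others were limma without a trend, with robust priors or with array weights, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were limma voom on the recovered reads, both libraries that stand apart left out together, and removal of trends with gene length and GC content by a spline with 5 degrees of freedom. Length and GC content were known for 99.52% of the genes tested. The procedure was tested on simulated data for 12746 genes, where limma recovered 54 of 100 genes changed by 1 on the log2 scale and 91 of 100 changed by 2, and called 7 of 12433 unchanged genes. The proteasome and oxidative phosphorylation lists were shifted by 0.5 and −0.5 in the same data. The simulated noise was independent between genes and alike in all libraries. Real libraries held correlated genes and libraries that stand apart, so these shares do not give the power in the real data.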

Results

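Messenger RNA was profiled by short-read sequencing in biopsies of vastus lateralis, a muscle of the front of the thigh, from 4 people without cirrhosis (controls) and 4 people with cirrhosis. Cirrhosis is an advanced scarring of the liver, and a scarred liver clears less ammonia from the blood. The series asks how skeletal muscle responds to raised ammonia, and the human part compares these 2 groups. Ammonia concentrations were not used here. The deposited values are FPKM, reads scaled by the length of the gene and by the number of counted reads. The numbers of counted reads, recovered from the values, were 23153678, 20272649, 24753733 and 21527003 in controls 1 to 4. They were 21268166, 24658385, 19799543 and 19678809 in cirrhosis libraries 1 to 4. At these depths a single read on a gene of 1 kilobase was worth between 0.0404 and 0.0508 FPKM. A mean FPKM of at least 1 over the 8 libraries was reached by 12746 genes, which were tested. Each log2 difference given here is cirrhosis minus control on the log2(FPKM + 1) scale, which understates the change of low genes.

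The libraries with cirrhosis did not form a single cluster. Pearson correlations of log2 values, computed across genes, ran from 0.911 to 0.978 between libraries of the same group and from 0.899 to 0.976 between groups. Cirrhosis replicate 4 lay at a score of −70.84 on the first principal component, which held 46.8% of the variance, and the others lay between −24.75 and 33.98. Cirrhosis replicate 3 lay at 43.57 on the second component, which held 16.6% of the variance. Cirrhosis replicates 1 and 2 lay among the controls on both components.

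**Figure D1:**
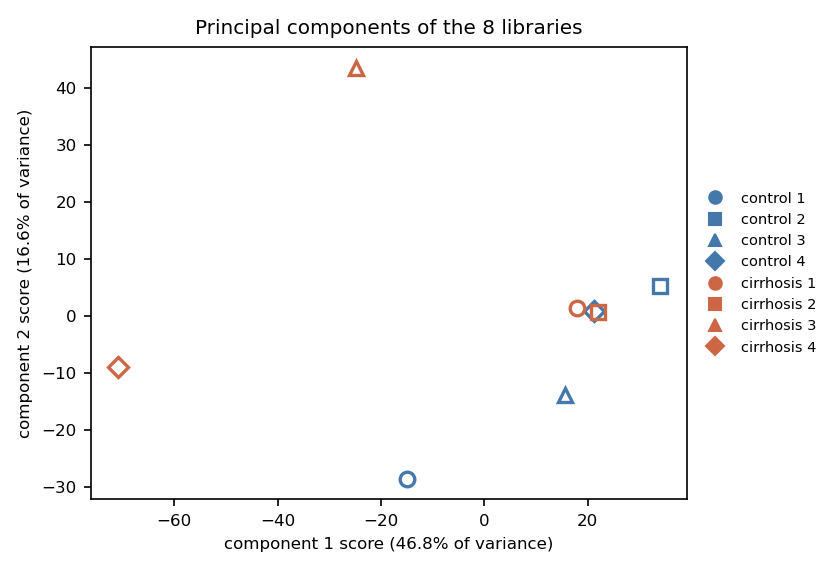
Scores of the 8 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 1), in component score units, with blue symbols for controls, orange symbols for cirrhosis and a symbol shape for each replicate number. Cirrhosis replicate 4 sits at −70.84 on component 1 and cirrhosis replicate 3 at 43.57 on component 2, while cirrhosis replicates 1 and 2 sit close to control replicate 4.

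The circadian clock, the set of transcription factors that drives daily rhythms of gene expression, was the list with the most members past the threshold when adjusted over the list alone. Of its 9 such members 2 were higher and 7 lower in cirrhosis. ARNTL (ENSG00000133794), which encodes the activator BMAL1, had a mean FPKM of 6.64 ± 2.44 (SD, n = 4) in controls and 16.1 ± 2.88 (n = 4) in cirrhosis. CIART (ENSG00000159208), a repressor of the activator complex, had 26.9 ± 5.17 (SD, n = 4) in controls and 4.95 ± 1.83 (n = 4) in cirrhosis. The period gene PER1 had 104.7 ± 39.1 (SD, n = 4) and 34.6 ± 14.8 (n = 4). Of the 46 gene lists tested, only the clock list passed the mixed test of fry, a rotation test of limma (adjusted p = 0.00369). The mixed test asks whether genes of a list change in either direction, and was not repeated under the alternative settings.

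Of the 19 measured clock genes, 9 passed the threshold of 0.05 when adjusted over the list alone and 0 passed when adjusted over all genes tested. Those 9 fell into a higher and a lower set. ARNTL differed by 1.20 (SE 0.23) and NFIL3, a repressor of the clock output genes, by 1.24 (SE 0.29) on the log2 scale, both above every control in all 4 cirrhosis libraries. The lower set held CIART at −2.28 (SE 0.27), PER1 at −1.59 (SE 0.42), DBP at −1.32 (SE 0.35), PER3 at −1.01 (SE 0.24), NR1D2 at −0.80 (SE 0.21), HLF at −0.78 (SE 0.23) and TEF at −0.74 (SE 0.17). DBP, TEF and HLF encode activators of clock output genes, and NR1D2 encodes a repressor of ARNTL. In CIART, PER3, NR1D2, HLF and TEF all 4 cirrhosis libraries lay below all 4 controls, while in PER1 and DBP the groups overlapped. The other 10 clock genes did not pass, among them CLOCK at 0.15 (SE 0.15), NPAS2 at 0.44 (SE 0.28), PER2 at −0.46 (SE 0.36) and NR1D1 at −0.35 (SE 0.45). The repressor genes CRY1, CRY2 and BHLHE40 were at 0.27 (SE 0.21), 0.18 (SE 0.21) and 0.20 (SE 0.27), on the side opposite to the period genes, while the repressor gene BHLHE41 was at −0.66 (SE 0.25). Of the 35 splits of the 8 libraries into 4 and 4, 4 had a list with at least 9 members past the threshold in this way, the real split included. As a list against all other genes the clock had a mean log2 difference of −0.33 by limma's camera test with a preset correlation (adjusted p = 0.00248), and an adjusted p = 0.78 with an estimated correlation. Without cirrhosis replicates 3 and 4 its mean was −0.45 (camera, adjusted p = 0.000297).

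**Figure D2:**
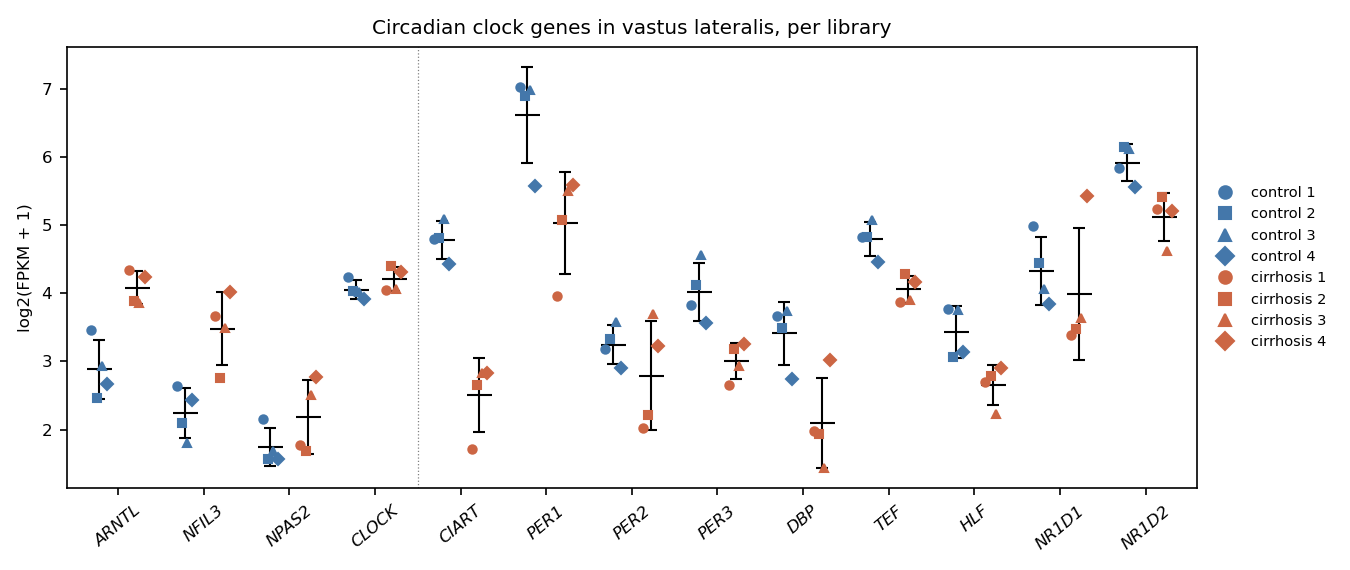
Levels of 13 clock genes as log2(FPKM + 1) on the y axis, by gene on the x axis, in each of the 8 libraries. Symbols are single libraries, horizontal bars are group means and error bars are SD over 4 libraries, with genes of the activator side and NFIL3 left of the dotted line. ARNTL sits higher in all 4 cirrhosis libraries than in all 4 controls and CIART, PER3, TEF, HLF and NR1D2 sit lower.

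Over single genes, 0 of 12746 passed the threshold of 0.05 by limma with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 754 genes, against 637 expected by chance, with 431 higher and 323 lower in cirrhosis. Rescaling the libraries by median ratios turned that split to 388 higher and 437 lower, so the balance between directions depended on the scaling. Of all genes tested, 59.97% were higher in cirrhosis, at a median log2 difference of 0.067, against 49.58% after that rescaling. The share was 49.43% without cirrhosis replicate 4. Counts of members higher or lower in a list are to be read beside these shares. CIART had the smallest adjusted p (limma, adjusted p = 0.131). It passed after median-ratio rescaling (limma, adjusted p = 0.0483) and without cirrhosis replicate 1 (limma, adjusted p = 0.0417), with adjusted p between 0.0417 and 0.773 over all alternatives. In 3.46% of genes the 2 groups did not overlap, and chance gives 2.86%.

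The 20 genes named by the rule for leading genes did not pass, and in each the groups did not overlap. Lower in all 4 cirrhosis libraries beside CIART were ING2, a chromatin regulator that binds methylated histone H3, at −1.17 (SE 0.18), SNAI3, a zinc finger repressor, at −1.38 (SE 0.28), and the serine protease gene PRSS23 at −1.31 (SE 0.27). SERPINA5, an inhibitor of serine proteases, had the lowest value of them at −2.47 (SE 0.55). The mitochondrial carrier gene SLC25A25 was at −1.44 (SE 0.32), DBNDD1 at −1.25 (SE 0.29), the hyaluronidase gene HYAL1 at −1.03 (SE 0.23), the magnesium transporter gene NIPAL1 at −0.98 (SE 0.21) and the ubiquitin ligase gene HECW2 at −0.85 (SE 0.20).

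Higher in all 4 cirrhosis libraries beside ARNTL were BMF, which encodes a cell death activator of the BCL2 family, at 1.22 (SE 0.23) and PIM1, a serine kinase gene, at 1.56 (SE 0.30). ARRDC4, an arrestin family gene linked to glucose uptake, was at 1.04 (SE 0.20). CHMP1B, of the membrane remodelling complex ESCRT-III, was at 0.75 (SE 0.14). The muscle regulatory factor gene MYF6 had a mean FPKM of 167 ± 18.4 (SD, n = 4) in controls and 287 ± 37.3 (n = 4) in cirrhosis, a log2 difference of 0.78 (SE 0.15). The imprinted gene NNAT was at 0.96 (SE 0.21), the cytokine receptor gene IL20RA at 1.09 (SE 0.24), TMCC3 at 0.80 (SE 0.18) and the transporter gene ABCC5 at 0.67 (SE 0.15).

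Genes of ammonia handling and of muscle mass, which the question of the series concerns, gave no difference past the threshold. GLUL encodes glutamine synthetase, the enzyme that fixes ammonia into glutamine, and had a mean FPKM of 279 ± 114 (SD, n = 4) in controls and 186 ± 66.4 (n = 4) in cirrhosis. MSTN encodes myostatin, a brake on muscle growth, and had 8.17 ± 3.76 (SD, n = 4) and 8.61 ± 10.5 (n = 4). Its log2 difference was −0.60 (SE 0.74), opposite in sign to the difference of the FPKM means, and 0.82 without cirrhosis replicates 3 and 4. The ubiquitin ligase genes of muscle atrophy, FBXO32 and TRIM63, differed by −0.22 (SE 0.47) and −0.62 (SE 0.28), with FBXO32 at 0.28 without cirrhosis replicate 3 and at 0.37 without cirrhosis replicates 3 and 4. ATF4, the transcription factor of the integrated stress response, differed by −0.47 (SE 0.21) and its partner gene DDIT3 by 0.06 (SE 0.15), the latter at −0.02 after median-ratio rescaling. PPARGC1A, a regulator of mitochondrial biogenesis, differed by −0.59 (SE 0.39), and by 0.17 without cirrhosis replicates 3 and 4. CDKN1A, which encodes the cell cycle inhibitor p21, had 4.97 ± 3.69 (SD, n = 4) and 33.0 ± 28.9 (n = 4), a log2 difference of 2.20 (SE 0.70), with the groups overlapping. Its FPKM was 10.05 and 7.83 in cirrhosis replicates 1 and 2, against 1.72 to 10.05 in controls. In cirrhosis replicates 3 and 4 CDKN1A was at 66.65 and 47.29. All 8 of these genes had an adjusted p of at least 0.734 by limma.

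The corresponding lists did not pass camera in all 8 libraries either. The list of ammonia, glutamine, urea and purine nucleotide cycle genes had 9 of 21 members higher and 12 lower, with a mean log2 difference of −0.06 (camera, adjusted p = 0.119). Its members with the smallest p were AMPD3, an AMP deaminase gene, at 1.98 (SE 0.57), and the arginase gene ARG2 at −1.39 (SE 0.53). Atrophy ligases and FOXO genes had a mean of 0.06 over 27 members (camera, adjusted p = 0.443) and integrated stress response genes 0.15 over 29 (camera, adjusted p = 0.357). The insulin, IGF1 and mTORC1 list had a mean of 0.12 over 38 members (camera, adjusted p = 0.442). The myostatin, activin and TGF-beta list had a mean of 0.15 over 34 members (camera, adjusted p = 0.495), and of 0.017 to 0.28 with 1 library left out. Autophagy and lysosome genes had 0.10 over 36 members (camera, adjusted p = 0.257), and proteasome subunits −0.03 over 37 (camera, adjusted p = 0.0815). With 1 library left out the mean ran from 0.0085 to 0.11 for atrophy genes, 0.047 to 0.17 for the insulin list and 0.043 to 0.13 for autophagy. Amino acid transporters had 0.14 over 22 (camera, adjusted p = 0.799) and branched-chain amino acid catabolism −0.13 over 25 (camera, adjusted p = 0.0628). The branched-chain list lay close to the threshold. It passed camera as lower under median-ratio rescaling (adjusted p = 0.0352), no filter (adjusted p = 0.0445), trend removal (adjusted p = 0.0173) and voom (adjusted p = 0.0403). It also passed without control replicate 1 or 4 or cirrhosis replicate 1 or 2, at means of −0.12, −0.18, −0.15 and −0.22, but had a mean of 0.0074 without cirrhosis replicate 3 (camera, adjusted p = 0.701). Proteasome subunits passed as lower without control replicate 1 or 3 or cirrhosis replicate 2 or 3, at means of −0.02, −0.048, −0.073 and −0.044, and had means of 0.017 without control replicate 4 and 0.01 without cirrhosis replicate 4.

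Genes of mitochondrial energy production were lower in cirrhosis as a group, in 2 of the 4 libraries. The call of the oxidative phosphorylation list by camera was lost with an estimated correlation (adjusted p = 0.78 with an estimated correlation). Of 78 nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 75 had a lower mean and 3 a higher mean. Their mean log2 difference was −0.37, with ATP5F1C, a subunit of ATP synthase, at −0.55 (SE 0.22) and the complex I subunit gene NDUFS8 at −0.48 (SE 0.18). Of 69 genes of the mitochondrial ribosome 56 were lower, with a mean of −0.18, and of 26 tricarboxylic acid cycle genes 23 were lower, with a mean of −0.28. In these lists 0 members passed, either adjusted over the list alone or over all genes. The mRNAs encoded in the mitochondrial genome had a mean of −0.04 over 13 members (camera, adjusted p = 0.443), and mitochondrial biogenesis genes −0.01 over 30 (camera, adjusted p = 0.348). The score of the mitochondrially encoded mRNAs was −0.63 in cirrhosis replicate 3 and 0.40 in cirrhosis replicate 4, with the other 6 libraries between −0.28 and 0.19. Other lists stood apart in the same 2 libraries. Cirrhosis replicates 3 and 4 had immediate early scores of 0.86 and 1.52, with the other 6 libraries between −0.74 and 0, and cirrhosis replicate 4 had scores of 2.67 for macrophage, 1.68 for T and NK cell markers and −1.41 for fast-fibre genes. The adipocyte score was 1.70 in cirrhosis replicate 4 and 1.66 in control replicate 1.

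Camera with a preset correlation gave adjusted p = 2.04e-19 for oxidative phosphorylation, 2.81e-08 for the mitochondrial ribosome and 1.21e-06 for the tricarboxylic acid cycle. The adjusted p was 0.78 with an estimated correlation for each, and the estimated correlation between members of the oxidative phosphorylation list was 0.73. The score of the oxidative phosphorylation list, its mean log2 deviation per library, was 0.18 ± 0.17 (SD, n = 4) in controls and −0.18 ± 0.43 (n = 4) in cirrhosis. It was −0.36 and −0.71 in cirrhosis replicates 3 and 4, and 0.17 and 0.16 in cirrhosis replicates 1 and 2. Without cirrhosis replicates 3 and 4 the mean log2 difference of the list was −0.016 (camera, adjusted p = 0.894), that of the mitochondrial ribosome −0.027 (camera, adjusted p = 0.721) and that of the tricarboxylic acid cycle −0.034 (camera, adjusted p = 0.759). With 1 library left out, oxidative phosphorylation was at −0.19 and the mitochondrial ribosome at −0.087 without cirrhosis replicate 4, and the tricarboxylic acid cycle at −0.17 without cirrhosis replicate 3, and all 3 still passed. Further mitochondrial members named by the rule were COX5A at −0.48 (SE 0.20), MRPL15 at −0.69 (SE 0.20), MRPS6 at −0.66 (SE 0.20), MRPL34 at −0.65 (SE 0.22), IDH2 at −0.56 (SE 0.25), MDH1 at −0.61 (SE 0.27) and IDH3A at −0.35 (SE 0.16).

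Glycolytic genes were lower in 22 of 29 members, with a mean log2 difference of −0.25 (camera, adjusted p = 0.00245, and adjusted p = 0.78 with an estimated correlation). The lactate and monocarboxylate transporter genes SLC16A1 and SLC16A3 were at −1.06 (SE 0.32) and −1.72 (SE 0.57), while PFKFB3, which makes an activator of glycolysis, was at 1.25 (SE 0.68). PFKFB3 ran from 0.71 to 1.83 with 1 library left out. The glycolysis score was 0.20 and −0.02 in cirrhosis replicates 1 and 2, and −0.34 and −0.35 in replicates 3 and 4. The mean was −0.18 without cirrhosis replicate 4 (camera, adjusted p = 0.119) and −0.03 without replicates 3 and 4 (camera, adjusted p = 0.999). Genes of the slow-fibre contractile apparatus had a mean of −0.24 over 17 members (camera, adjusted p = 0.00763, and adjusted p = 0.793 with an estimated correlation). Among them PLN, the inhibitor of the sarcoplasmic calcium pump, was at −1.53 (SE 0.56), the myosin light chain gene MYL3 at −0.72 (SE 0.27) and TNNC1 at −0.52 (SE 0.33). Fast-fibre genes had a mean of −0.27 over 16 members (camera, adjusted p = 0.0486, and adjusted p = 0.793 with an estimated correlation), with CASQ1 at −0.51 (SE 0.37), MYH1 at −1.01 (SE 1.01) and ACTN3 at −0.67 (SE 0.69). The fibre scores went apart within the cirrhosis group. The slow-fibre score was −1.10 in replicate 1 and 0.63 in replicate 4, and the fast-fibre score was 0.71 in replicate 1 and −1.41 in replicate 4. Without cirrhosis replicate 4 the fast-fibre mean was 0.16 (camera, adjusted p = 0.129) and the slow-fibre mean −0.49 (camera, adjusted p = 4.58e-05). Without cirrhosis replicate 1 the slow-fibre mean was 0.087 (camera, adjusted p = 0.919), and without replicates 3 and 4 it was −0.53 (camera, adjusted p = 2.31e-06). The fast-fibre list also lost its call without control replicate 2, 3 or 4 or cirrhosis replicate 2, at means of −0.28, −0.20, −0.24 and −0.28. It lost it as well by camera with a mean FPKM of at least 5 (adjusted p = 0.117), median-ratio rescaling (adjusted p = 0.118), quantile normalization (adjusted p = 0.416), trend removal (adjusted p = 0.0954) and voom (adjusted p = 0.123). Array weights gave a fast-fibre mean of 0.069 (camera, adjusted p = 0.957). The slow-fibre list lost its call under quantile normalization, at −0.16 (camera, adjusted p = 0.161), and glycolysis with array weights, at −0.11 (camera, adjusted p = 0.115). Fatty acid oxidation genes had a mean of 0.00 over 32 members (camera, adjusted p = 0.216).

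Inflammatory gene groups were higher in cirrhosis, most of all in a single library. All 34 measured genes of the interferon response had a higher mean in cirrhosis, with a mean log2 difference of 0.99 (camera, adjusted p = 1.54e-09, and adjusted p = 0.78 with an estimated correlation). IRF9, a subunit of the interferon-activated transcription complex, had a mean FPKM of 0.808 ± 0.205 (SD, n = 4) in controls and 2.94 ± 1.58 (n = 4) in cirrhosis. IRF7 was at 1.23 (SE 0.51) and the peptide transporter gene TAP1 at 1.21 (SE 0.55) on the log2 scale. TAP1 ran from 0.56 to 1.54 with 1 library left out. Its FPKM was 48.5 in cirrhosis replicate 4, against 5.44, 8.11 and 7.79 in cirrhosis replicates 1 to 3. Of 23 genes of NF-kappaB and inflammatory cytokines 22 were higher, with a mean of 0.64 (camera, adjusted p = 1.97e-05, and adjusted p = 0.78 with an estimated correlation). IL6R, the interleukin 6 receptor gene, was at 0.71 (SE 0.16). It passed when adjusted over the list alone (limma, adjusted p = 0.04) but not over all genes (limma, adjusted p = 0.734). IL6R was highest in cirrhosis replicate 1, with FPKM of 26.1, 22.5, 18.0 and 19.8 in cirrhosis replicates 1 to 4, against 11.05 to 15.46 in controls. The chemokine genes CCL2 and CXCL2 were at 1.71 (SE 0.55) and 1.54 (SE 0.55).

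Markers of macrophages and monocytes were high together with these lists in cirrhosis replicate 4. All 14 had a higher mean in cirrhosis, with a mean log2 difference of 0.79 (camera, adjusted p = 0.0278, and adjusted p = 0.793 with an estimated correlation). In cirrhosis replicate 3 the macrophage score was −0.44, while the interferon score was 0.23 and the NF-kappaB score 0.39. The complement genes C1QB and C1QA, made by macrophages, were at 1.64 (SE 0.89) and 1.23 (SE 0.81), and the lysozyme gene LYZ was at 1.16 (SE 0.77). The macrophage score was 2.67 in cirrhosis replicate 4 and between −0.52 and −0.13 in the other 3 cirrhosis libraries, against −1.43 to 0.44 in controls. In the same library the interferon score was 2.25, the NF-kappaB score 1.37 and the score of T and NK cell markers 1.68, against −0.56 to 0.07 for T and NK cells in the other cirrhosis libraries. Without cirrhosis replicate 4 the macrophage list had a mean of 0.033 (camera, adjusted p = 0.853), the interferon list 0.41 (camera, adjusted p = 8.22e-08) and the NF-kappaB list 0.30 (camera, adjusted p = 0.00033). The interferon scores of cirrhosis replicates 1, 2 and 3 were −0.56, 0.06 and 0.23, against −0.99 to −0.15 in controls. The macrophage list also lost its call without control replicate 2 or 3, at means of 0.45 and 0.76, and with array weights, at 0.46. Without cirrhosis replicates 3 and 4 the interferon mean was 0.24 (camera, adjusted p = 0.00088), the NF-kappaB mean 0.04 (camera, adjusted p = 0.336) and the macrophage mean 0.07 (camera, adjusted p = 0.742).

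Genes of denervation and regeneration were higher in cirrhosis as a group, in the same 2 libraries that had lower mitochondrial scores. Of 24 members 22 had a higher mean, with a mean log2 difference of 0.78 (camera, adjusted p = 2.71e-04, and adjusted p = 0.78 with an estimated correlation). MYF6 passed when adjusted over the list alone (limma, adjusted p = 0.0128) but not over all genes (limma, adjusted p = 0.734). The stress gene GADD45A was at 1.57 (SE 0.47) and HDAC9, a repressor of muscle gene programmes, at −0.81 (SE 0.23). The list's score was 1.02 and 1.26 in cirrhosis replicates 3 and 4, and between −0.71 and −0.09 in the other 6 libraries. In those 2 libraries immediate early scores were 0.86 and 1.52 (others −0.74 to 0) and heat shock scores 0.48 and 0.27 (others −0.35 to 0.05), and replicate 4 had scores of 2.67 for macrophage and 1.68 for T and NK cell markers. Satellite cell markers, of the stem cells of muscle, were higher in 12 of 12 members with a mean of 0.45 (camera, adjusted p = 0.00778, and adjusted p = 0.78 with an estimated correlation). Among them SPRY1 was at 0.68 (SE 0.23), MYF5 at 0.71 (SE 0.26) and VCAM1 at 1.02 (SE 0.43). Targets of p53 and genes of cell cycle arrest were higher in 24 of 30 members with a mean of 0.31 (camera, adjusted p = 0.0278, and adjusted p = 0.793 with an estimated correlation). MDM2, which encodes the ubiquitin ligase of p53, was at 0.85 (SE 0.20) and SESN2, an inhibitor of mTORC1, at 0.62 (SE 0.17), both above every control in all 4 cirrhosis libraries. Without cirrhosis replicates 3 and 4 none of these 3 lists passed camera, with adjusted p of 0.467, 0.452 and 0.336 in that order. The p53 list also lost its call without control replicate 2 or 4 or cirrhosis replicate 3, at means of 0.19, 0.25 and 0.28, and with a mean FPKM of at least 5 or array weights, at 0.28 and 0.21. Without cirrhosis replicate 4 the denervation, satellite cell and p53 means were 0.49, 0.25 and 0.17.

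**Figure D3:**
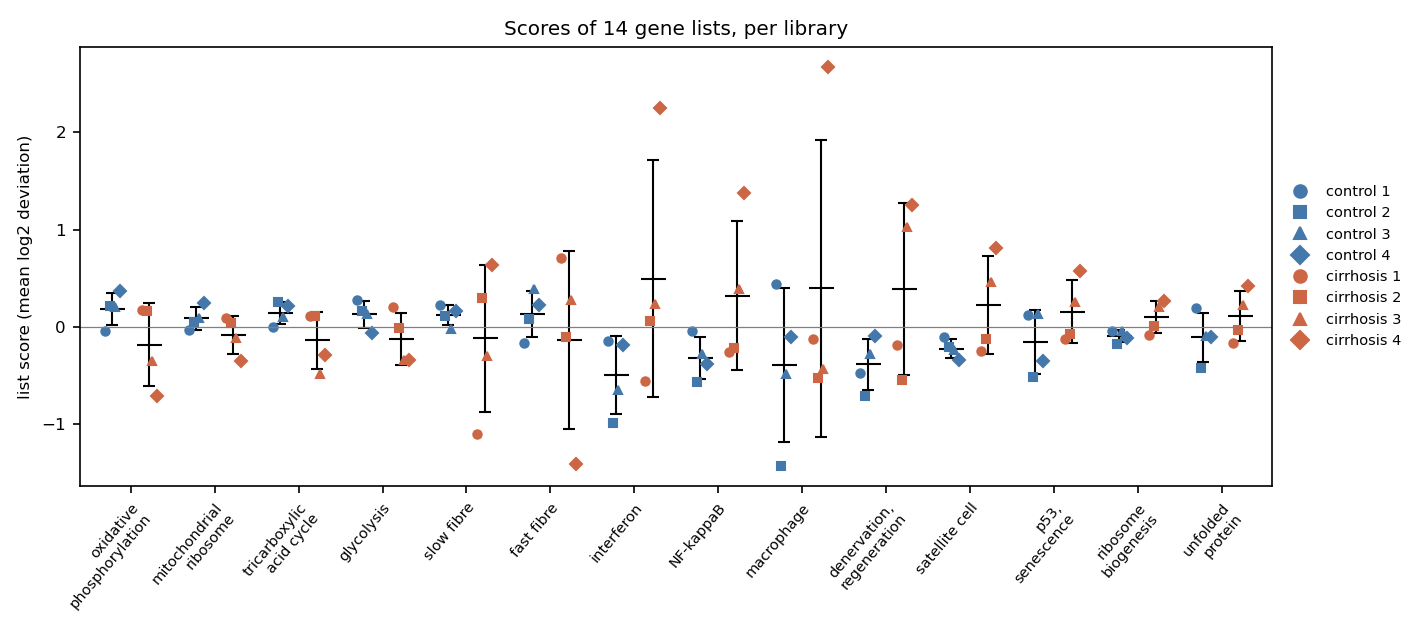
Scores of 14 gene lists on the y axis, each the mean log2 deviation of the list's genes from their mean over the 8 libraries, by list on the x axis. Symbols are single libraries, horizontal bars are group means and error bars are SD over 4 libraries. Cirrhosis replicate 4 sits at 2.25 in the interferon list and at 2.67 in the macrophage list, and cirrhosis replicates 3 and 4 sit at −0.36 and −0.71 in oxidative phosphorylation.

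Genes of protein synthesis and folding differed by small amounts, and replication-dependent histone genes by more. For comparison, 59.97% of all genes tested were higher in cirrhosis. Ribosome biogenesis genes were higher in 25 of 29 members with a mean log2 difference of 0.19 (camera, adjusted p = 0.0278, and adjusted p = 0.793 with an estimated correlation), with NAT10, an RNA acetyltransferase gene, at 0.46 (SE 0.16), NOP56 at 0.49 (SE 0.18) and PES1 at 0.52 (SE 0.21). Genes of the endoplasmic reticulum unfolded protein response were higher in 23 of 26 members with a mean of 0.22 (camera, adjusted p = 0.0278, and adjusted p = 0.793 with an estimated correlation), with CRELD1 at 0.53 (SE 0.19), the stress sensor genes ERN1 at 0.55 (SE 0.22) and EIF2AK3 at 0.52 (SE 0.23). Cytosolic ribosomal protein genes were lower in 53 of 79 members with a mean of −0.06 (camera, adjusted p = 0.00647, and adjusted p = 0.793 with an estimated correlation), with RPS26 at −0.32 (SE 0.22), RPS29 at −0.30 (SE 0.22) and RPS4X at −0.23 (SE 0.17). Replication-dependent histone genes were lower in 7 of 8 members with a mean of −0.42 (camera, adjusted p = 0.00269, and adjusted p = 0.78 with an estimated correlation), with HIST1H2BD at −0.59 (SE 0.32), HIST1H3E at −0.60 (SE 0.36) and HIST1H4H at −0.53 (SE 0.36). Without cirrhosis replicates 3 and 4 the means were 0.056 for ribosome biogenesis (camera, adjusted p = 0.336), 0.0091 for the unfolded protein response (camera, adjusted p = 0.839) and 0.066 for histones (camera, adjusted p = 0.564). Cytosolic ribosomal proteins still passed there, at −0.076 (camera, adjusted p = 0.0428). With 1 library left out, the unfolded protein response lost its call without control replicate 2 or 3 or cirrhosis replicate 2, 3 or 4, at means of 0.11, 0.22, 0.27, 0.18 and 0.12. Ribosome biogenesis lost it without control replicate 1 or cirrhosis replicate 2 or 3, at 0.21, 0.22 and 0.16, and histones without cirrhosis replicate 4, at −0.30. Histones kept their call at −0.22 without cirrhosis replicate 3 and at −0.66 without cirrhosis replicate 1. Cytosolic ribosomal proteins lost it without control replicate 3 or 4 or cirrhosis replicate 2 or 4, at 0.009, −0.052, −0.039 and 0.027. They also lost it under quantile normalization, at −0.012 (camera, adjusted p = 0.75), and with array weights, at −0.028 (camera, adjusted p = 0.113). Array weights ended the calls of the unfolded protein response, ribosome biogenesis and histones too, at 0.13, 0.12 and −0.17. A mean FPKM of at least 5 ended that of the unfolded protein response, at 0.18, and median-ratio rescaling and voom that of ribosome biogenesis, at 0.12 and 0.13.

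In all, 17 of the 46 lists passed camera with a preset correlation, 8 higher and 9 lower, and 0 passed with an estimated correlation or in the directional test of fry. Exact two-sided permutation of the list scores over the 70 assignments gave 0 lists past the threshold after adjustment, and 0.0286 is the smallest p these permutations can give. No list reached that value. The smallest unadjusted permutation p was 0.0857, for the circadian clock and ribosome biogenesis lists, and it was 0.171 for oxidative phosphorylation. Among markers of other cells, adipocyte genes had a mean log2 difference of −0.30 over 13 members, T and NK cell genes 0.41 over 11, neutrophil and mast cell genes 0.30 over 10 and erythroid and platelet genes 0.76 over 5. Endothelial genes had a mean of 0.09 over 14, smooth muscle and pericyte genes −0.11 over 12, fibroblast genes 0.08 over 15 and Schwann and nerve genes −0.22 over 9. None of these 8 cell type lists passed camera, with adjusted p between 0.133 and 0.835, in all 8 libraries. Without cirrhosis replicate 4 the adipocyte mean was −0.98 (camera, adjusted p = 4.58e-05) and the erythroid and platelet mean 1.40 (camera, adjusted p = 0.00033). Camera with an estimated correlation was not run with libraries left out, so such calls rest on the preset of 0.01. In all 8 libraries the estimated correlation was 0.65 in the adipocyte list and 0.86 in the erythroid and platelet list. Adipocyte scores still overlapped, at −0.72 in control replicate 2 and −0.66 in cirrhosis replicate 3. The erythroid and platelet score was 2.29 in cirrhosis replicate 3 and 0.93 in replicate 1, against 0.82 in control replicate 1, and the mean was 0.38 without control replicate 2 (camera, adjusted p = 0.468). Without cirrhosis replicate 3 too few of its members reached the filter for a test. Array weights gave calls for adipocyte, erythroid and platelet, neutrophil and mast cell and extracellular matrix genes, at −0.54, 1.17, 0.39 and 0.30. The adipocyte mean was 0.21 without control replicate 1, −0.59 without control replicate 2 (camera, adjusted p = 0.04) and −1.04 without cirrhosis replicates 3 and 4 (camera, adjusted p = 0.000592). T and NK cell genes were at 0.67 without cirrhosis replicate 3 (camera, adjusted p = 0.00606) and −0.19 without cirrhosis replicate 4. Neutrophil and mast cell genes passed at 0.52 without control replicate 1 (camera, adjusted p = 0.0276), at 0.48 without cirrhosis replicate 3 (camera, adjusted p = 0.0139) and at 0.30 without cirrhosis replicates 3 and 4 (camera, adjusted p = 0.0428). Endothelial genes passed at 0.27 without control replicate 1 (camera, adjusted p = 0.0429), and Schwann and nerve genes at −0.19 with no filter (camera, adjusted p = 0.0102). In all, 9 of the 17 lists past camera lost their call when some single library was left out, and 14 of the 29 others gained one.

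The sirtuin and NAD list had a mean of −0.06 over 20 members, immediate early genes 0.57 over 22, DNA repair 0.13 over 44 and extracellular matrix genes 0.24 over 39, and none of these 4 passed camera in all 8 libraries, with adjusted p between 0.054 and 0.205. Extracellular matrix genes passed at 0.54 without control replicate 1 (camera, adjusted p = 6.27e-05) and at 0.42 without cirrhosis replicate 2 (camera, adjusted p = 0.0494), and were at −0.016 without control replicate 2. Immediate early genes passed as higher without control replicate 1 or cirrhosis replicate 1 or 2, at 0.67, 0.87 and 0.79. They were at 0.12 without cirrhosis replicate 4 (camera, adjusted p = 0.559), and passed as lower without cirrhosis replicates 3 and 4, at −0.36 (camera, adjusted p = 0.0428). They also passed as higher after median-ratio rescaling (camera, adjusted p = 0.0212). DNA repair passed at 0.18 and 0.15 without control replicate 3 or cirrhosis replicate 3, and the sirtuin and NAD list at −0.032 and −0.064 without control replicate 1 or cirrhosis replicate 1. In 5 further lists without a call, the camera test pointed lower while the mean was above 0. These were fatty acid oxidation, antioxidant and NRF2 targets at 0.05, glucocorticoid targets at 0.07, HIF1 targets at 0.14 and heat shock proteins at 0.08, with camera adjusted p between 0.216 and 0.904. Camera compares a list with all other genes, and the median log2 difference over all genes tested was 0.067. Heat shock proteins passed as lower at −0.062 without cirrhosis replicate 3 (camera, adjusted p = 0.035) and at −0.25 without cirrhosis replicates 3 and 4 (camera, adjusted p = 0.000297). Fatty acid oxidation passed as lower at −0.029 without control replicate 1 (camera, adjusted p = 0.0219) and at −0.097 without cirrhosis replicate 2 (camera, adjusted p = 0.0291). Without cirrhosis replicates 3 and 4, 2 lists passed camera as higher and 6 as lower.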

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

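The tests chosen after the result was seen are the splits for genes past the threshold and for the best list, the clock in cirrhosis replicates 1 and 2, the clock with all members by role, time of day, the mitochondrial lists without cirrhosis replicates 3 and 4, and both tests of the inflammatory lists. The 8 libraries can be split into 4 against 4 in 35 ways. For genes past the threshold by limma the real split gave 0 and the highest other split 0, so all 35 gave as many by construction and the splits say nothing about chance there. At an unadjusted p under 0.05 the real split gave 754 genes, 10 of 35 splits gave as many and the highest other split gave 2259, so chance cannot be excluded and that split points to a structure of the samples. The number of lists past camera was 17, the highest other split gave 23 and 18 of 35 gave as many, so chance cannot be excluded for it either.

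The circadian clock list had 9 members past the threshold when adjusted over the list alone, against 4 in the highest other split (1 of 35 gave as many), but the list was picked as the one with most such members, and scored on its own best list 4 of 35 splits gave as many, with 14 in the highest other, so chance cannot be excluded. A contrast of ARNTL, CLOCK, NPAS2 and NFIL3 less PER1, PER2, PER3, NR1D1, NR1D2, DBP, TEF, HLF and CIART, picked after their values were seen, differed by 1.79, and by 0.95 with all 19 members placed by known role (CRY1, CRY2, BHLHE40 and NFIL3 among the repressors), where 4 of 4 cirrhosis libraries still lay above the highest control. In the picked contrast cirrhosis replicates 1 and 2 (2 of 2) lay above the highest control, but its genes were chosen with these libraries in view. With all members placed by role, replicates 1 and 2 lay at 0.88 and 0.49, and the highest control at −0.33. Without replicates 3 and 4, 11 members passed. These values argue against libraries that stand apart as the whole cause. Trends with gene length and GC content are argued against too, since 10 members passed after their removal. The picked contrast was then 1.86. A different time of day of the biopsies in the 2 groups may also give this pattern and cannot be told apart from cirrhosis, as the labels used here give no times. The exact two-sided permutation p of the difference was 0.0286, the smallest 4 against 4 can give, on genes chosen after the pattern was seen.

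The oxidative phosphorylation list was lower by a mean log2 difference of −0.37. Trends with gene length and GC content are argued against as the whole cause, since the mean was −0.38 after their removal (camera, adjusted p = 8.38e-13, and adjusted p = 0.78 with an estimated correlation before it). The removal also moved the median over all genes from 0.067 to 0.0064, so these 2 means have different baselines, and a part played by the trends is not excluded. Cirrhosis replicates 3 and 4 may carry the difference, since the mean without them was −0.016 (camera, adjusted p = 0.894). Those libraries also had immediate early scores of 0.86 and 1.52, and replicate 4 a macrophage score of 2.67. Whether they differ in the disease, the biopsy or its handling was not tested and stays open.

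The interferon, NF-kappaB and macrophage lists were higher, most of all in cirrhosis replicate 4. This library may carry much of the interferon difference, since the mean of 0.99 was 0.41 without it (camera, adjusted p = 8.22e-08), and adjusted p = 0.78 with an estimated correlation in all 8 libraries. The interferon score of cirrhosis replicate 1, −0.56, lay within the control range. In cirrhosis replicate 4 the macrophage score less the endothelial score was 2.42, and between −1.23 and 0.03 in the other 7 libraries (SD 0.46). This argues against a lower share of muscle fibres with all other cells raised alike as the whole cause. It cannot exclude a lower fibre share with some other cells raised more than endothelial cells. That library had scores of 1.70 for adipocyte and 1.68 for T and NK cell markers, −1.41 for fast-fibre and 0.63 for slow-fibre genes. A rise in macrophages themselves, in the muscle or in the piece sampled, stays open and was not tested.

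Of 254 groups of 4 libraries examined, 17 had a single library far from the other 3, and chance gives about 1 in 20, or 12.7. Cirrhosis replicate 4 was that library in 7 of them and a control in 7. In cirrhosis replicate 4, log2(FPKM + 1) was 4.5 for TMCC3 (others 3.93 to 3.98), 5.63 for TAP1 (2.69 to 3.19) and 10.32 for CASQ1 (11.75 to 11.92). Its scores were 0.23 for DNA repair (others 0 to 0.02), 1.7 for adipocyte markers (−0.83 to −0.66) and 2.67 for macrophage markers (−0.52 to −0.13). It had 13658 genes at an FPKM of at least 1, against 12266 to 12502 in the other cirrhosis libraries. Cirrhosis replicate 1 had 4.68 for CHMP1B (others 5.03 to 5.05) and 1.71 for CIART (2.66 to 2.83), and cirrhosis replicate 2 had 4.76 for IDH3A (5.02 to 5.06). Control replicate 2 had 6.18 for PPARGC1A (others 5.56 to 5.63), 7.08 for RPS26 (7.71 to 7.79), 7.61 for RPS29 (7.99 to 8.04), 4.86 for NOP56 (5.21 to 5.23) and 4.23 for CRELD1 (4.65 to 4.7). Control replicate 3 had 6.75 for ATF4 (others 7.45 to 7.6) and control replicate 1 had 1.93 for ERN1 (1.74 to 1.76).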

How the results depend on the processing

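Voom on the recovered reads, the removal of length and GC trends, and leaving out cirrhosis replicates 3 and 4 together were chosen after seeing the data. Depth sets what low genes can show, at 0.0404 to 0.0508 FPKM per read and kilobase. Over processing alternatives, 1021 of 1032 comparisons of the 75 named genes kept their direction and side of the threshold, and 593 of 597 did so when 1 library was left out. For the 17 lists past camera these were 188 of 254 and 110 of 136, and for the 29 other lists 386 of 428 and 179 of 231. None of the 75 named genes passed with all libraries, so to keep their side meant to stay without a call. The 10 leading genes in each direction were chosen for groups that do not overlap, so they could not turn when 1 library was left out. The gene counts are therefore no measure of how firm the gene differences are. Where no cause is given here, the cause was not tested.

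Genes lower numbered 1 instead of 0 under median-ratio rescaling (CIART), and 0 to 1 with 1 library left out, with 1 without cirrhosis replicate 1 (CIART) and 1 without cirrhosis replicate 2 (a pseudogene). Genes higher numbered 0 by limma in every alternative, with 754 genes at an unadjusted p under 0.05 in all 8 libraries. That number was 435 without control replicate 2, 1249, 1490, 496 and 499 without cirrhosis replicates 1 to 4 in turn, 408 without both 3 and 4, and 1445 with no filter, which tests more genes. Lists higher, 8 with all libraries, numbered 5 to 12 with 1 library left out, with 5 without control replicate 2 and 12 without control replicate 1. They numbered 2 without cirrhosis replicates 3 and 4, 0 by camera with an estimated correlation and 0 by fry. Lists lower, 9 with all libraries and 6 to 13 with 1 left out, numbered 0 by camera with an estimated correlation and 0 by fry. The estimated correlation widens the test by construction. Camera takes no robust priors, so these were not run for lists. With the replicate number as a block, limma gave 0 genes, smallest adjusted p 0.58, and camera 10 lists higher and 11 lower, while deviations within same-numbered pairs correlated at −0.31, 0.32, −0.17 and −0.16, and 2 libraries had their own number as best match.

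The camera test of a list turned direction, at these mean log2 differences, without cirrhosis replicates 3 and 4: ammonia −0.019, branched-chain amino acids 0.023, endothelial −0.11, fast-fibre 0.17, fatty acid oxidation 0.048, glucocorticoid targets 0.0088, immediate early −0.36, integrated stress response −0.18, mitochondrial biogenesis 0.052, mitochondrially encoded 0.062, myostatin −0.0085, proteasome 0.0098 and histones 0.066. So did the genes ACTN3 at 0.10, FBXO32 at 0.37, HIST1H3E at 0.023, MSTN at 0.82, MYH1 at 0.96 and PPARGC1A at 0.17. Array weights turned MSTN to 0.21 and MYH1 to 0.13, and DDIT3 went to −0.016 under median-ratio rescaling and −0.018 under voom. Quantile normalization turned the tests of antioxidant genes at 0.058, heat shock proteins at 0.10 and mitochondrially encoded mRNAs at 0.034. A mean FPKM of at least 5 turned HIF1 targets at 0.18 and heat shock proteins at 0.079, and trend removal the endothelial list at −0.016. Fry, which does not compare a list with other genes, pointed higher for HIF1 targets at 0.14, glucocorticoid targets at 0.066 and heat shock proteins at 0.082.

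With 1 library left out the test turned direction at least once in these lists, whose means ran as follows: HIF1 targets 0.024 to 0.25, T and NK cells −0.19 to 0.67, amino acid transporters 0.034 to 0.24, antioxidant −0.074 to 0.14, cytosolic ribosomal proteins −0.16 to 0.027, endothelial −0.017 to 0.27, extracellular matrix −0.016 to 0.54, fast-fibre −0.55 to 0.16, fatty acid oxidation −0.10 to 0.12, fibroblast −0.27 to 0.41, glucocorticoid targets −0.022 to 0.17, heat shock proteins −0.062 to 0.21, integrated stress response 0.021 to 0.28, mitochondrially encoded −0.17 to 0.17, proteasome −0.073 to 0.017 and smooth muscle −0.31 to 0.28. The genes were ACTN3 at −1.21 to 0.045, DDIT3 at −0.042 to 0.12 and FBXO32 at −0.48 to 0.28.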

Other observations

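Genes of metal and hormone response held further members past the threshold when adjusted over the list alone, and 0 when adjusted over all genes tested. The metallothionein genes MT2A and MT1E, whose proteins bind zinc and copper, had log2 differences of 1.58 (SE 0.45; limma, adjusted p = 0.0301 over the list alone) and 1.49 (SE 0.49; limma, adjusted p = 0.0322), with overlapping groups. Their list had a mean of 0.68 over 5 members (camera, adjusted p = 0.0815), and passed without control replicate 1 at 0.81 and without cirrhosis replicate 1 at 0.90. Among glucocorticoid targets, KLF15 had a mean FPKM of 24.7 ± 10.7 (SD, n = 4) in controls and 9.29 ± 2.07 (n = 4) in cirrhosis, and passed over the list alone with MT2A and PER1, each at the same value (limma, adjusted p = 0.0481). LAMA2, a laminin of the muscle basement membrane, passed over the fibroblast list alone at 0.86 (SE 0.22; limma, adjusted p = 0.0484) and lay above every control in all 4 cirrhosis libraries.

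Some genes outside the naming rule, chosen after their values were seen, had large differences that did not pass over all genes. TFRC, the transferrin receptor that takes up iron, had a mean FPKM of 226 ± 43.2 (SD, n = 4) in controls and 62.1 ± 65.6 (n = 4) in cirrhosis, with every cirrhosis library below every control. The embryonic myosin heavy chain gene MYH3, a marker of regenerating fibres, had 6.97 ± 2.91 (SD, n = 4) in controls, and 10.8, 5.59, 43.3 and 366.9 in cirrhosis replicates 1 to 4. The immediate early gene FOS had 3.21 ± 0.992 (SD, n = 4) in controls, and 4.83, 1.34, 107.7 and 235.6 in cirrhosis replicates 1 to 4. The score of its list was −0.74 and −0.49 in cirrhosis replicates 1 and 2, at or under every control, and the list's mean was −0.36 without cirrhosis replicates 3 and 4. The mitochondrial uncoupling protein gene UCP3 and the pyruvate dehydrogenase kinase gene PDK4, both induced in fasting, had log2 differences of 0.90 (SE 0.26) and 1.19 (SE 0.44), with overlapping groups.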
